A study of Danio rerio with 8 samples.

How the data were processed

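The series holds 8 RNA-seq libraries of zebrafish trunk tissue at 38 to 40 hours after fertilisation, 2 for each combination of genotype (foxc1a p162 homozygotes, MUT, or siblings, SIB) and region (anterior segments, AS, or posterior segments, PS). Groups were read from the library titles. The characteristics in the labels give the siblings as p162 heterozygotes, while the design text calls the control samples wild type; the control group is named SIB here, and its genotype remains as the labels state it. Per the labels' protocols, embryos were raised at 28 °C, heads and yolks were removed, tissue was kept in RNAlater for up to 2 days at 4 °C, RNA had an integrity number of at least 8, and stranded poly(A) libraries were made with the Illumina TruSeq kit and 15 PCR cycles. Paired-end reads came from an Illumina HiSeq sequencer, of 100 bp per the design text and 101 bp per the labels' protocols. Per the design text, reads were aligned to the Zv9 (danRer7) genome with RUM, which assigned each read to a single transcript. The version of RUM is not given in the sources used here.

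Per the file headers, the authors deposited 1 table of RefSeq transcripts whose expression columns are log2(RPKM + 1), where RPKM is reads scaled to transcript length and to the mapped reads of the library. The deposited table also has 4 columns that the authors call fold change. Each is the ratio of a sibling log2 value to a mutant log2 value with 0 replaced by 0.1, which held in all 58324 cells tested at a tolerance of 1e-05, so it is not a ratio of RPKM and was not used here. For star the authors' ratio is 4.94 in replicate 1 where the ratio of RPKM is 14.2, and for myhz1.2 it is 1.18 where the ratio of RPKM is 2.49. Of 14809 rows of the table, 228 at its end repeat the same fill value in every row of a column and were left out. Of the 14581 transcripts used, 351 are 0 in all libraries, 965 are further copies of a transcript, 15 are merged transcripts, 107 have no symbol and 10 carry a date in place of a symbol. The accessions of 13710 transcripts (94.0%) were found in a reference annotation, which served only for symbols. That annotation is of another genome build, and no genome was at hand, so no coordinates are given. The authors' table marks 129 transcripts of 112 symbols with the axon guidance term, where the design text counts 116 genes.

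The table holds no counts, so intervals for counting error could not be computed. RPKM values below 100 are multiples of 0.0001, within a tolerance of 0.01 of this step. The value of 1 read was estimated from the steps of lowly expressed transcripts, relative to the deepest library and up to a factor of 2. By this measure MUT_AS replicate 3 has 46.9 times fewer reads than the deepest library, SIB_PS replicate 3. Within groups, values across transcripts correlated with r = 0.962 in MUT_AS, 0.989 in MUT_PS, 0.990 in SIB_AS and 0.991 in SIB_PS. No columns were copies of each other.

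The groups, the comparisons, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated otherwise. The design provided for counts or normalized values, and since the table holds log2 values the limma route of the design was used. Transcripts with a mean of at least 1 RPKM over the 8 libraries (10889) were fitted with limma 3.58.1 in R 4.3.3, with statmod 1.5.0, on log2(RPKM + 1) with 1 mean per group, and the spread was moderated with trend and robust options. Log2 differences are therefore on the RPKM + 1 scale and understate ratios of low values. The contrasts were MUT against SIB in AS and in PS, AS against PS in SIB and in MUT, and the interaction of genotype and region. Benjamini-Hochberg adjusted p values under 0.05 over all transcripts were called, with no fold minimum. With 2 libraries per group, all 8 shared 1 estimate of the spread. A table of simulated data was tested in the same way, with 5 sets of 10889 transcripts that kept the spread of each group. Each set held 200 changed genes, drawn among transcripts with a mean log2 value above 3. At log2 changes of 1, 2 and 3 the fit recovered 74.3%, 99.4% and 99.4% of changed genes in the AS comparison and 74.6%, 99.4% and 99.4% in PS. Lower transcripts, such as star and cldn11a, were not covered. With fewer changed genes the adjusted threshold is stricter, so recovery would be lower. False calls made up 16.0% of calls in AS and 1.1% in PS. A fit with a weight per group gave 6.7% and 6.3% false calls and recovered 61.5% and 97.6% of genes at a change of 1. A list shifted lower was found in 5 of 5 sets. The noise was drawn independently for each gene and no unshifted list was tested, so false calls of lists of correlated genes were not checked.

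Lists of genes (28) were tested with camera of limma at a preset correlation of 0.01, which compares a list with all other genes, and adjusted over the lists within a contrast. Camera with a correlation estimated from the data and fry were run beside it. Fry tests whether a list's genes move, on balance, in the same direction and does not compare the list with other genes. No list passed under an estimated correlation in any contrast. Members past the threshold were counted over all genes tested and adjusted over the list alone, with the transcript of the highest mean for each symbol. The lists are axon guidance, somite segmentation and Foxc, dermomyotome and sclerotome, fast muscle, slow muscle, myogenic regulators, motor neuron, pan-neuronal, spinal progenitor and glia, pigment cell, endothelium, erythroid, myeloid, pectoral fin bud, pronephros, heart, liver gut and pancreas, periderm and epidermis, notochord, connective tissue matrix, hox paralog groups 1 to 5, 6 to 8 and 9 to 13, eye and brain, retinoic acid pathway, immediate early and heat shock, p53 pathway and cell death, and cell cycle. A list of heme synthesis genes and the axon guidance term of the authors' table were added after the data were seen.

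Named genes were foxc1a and foxc1b. Further named genes were, per contrast and direction, the 10 called genes (5 for the regional contrast in mutants and for the interaction) with the largest log2 difference, a mean of at least 5 RPKM, values of the 2 groups that do not overlap and a symbol that is not a clone name. Where fewer than 5 passed in a direction, the 5 with the smallest p that met the other conditions were named, as values that did not pass. In each list up to 4 members with the smallest p were named. The minimum of 5 in the deposited unit was read as RPKM. The alternatives were median scaling, no filter, a mean of at least 5 RPKM, pseudocounts of 0.1 and 0.5, an absolute log2 difference of at least 1, the title ending as a replicate block, only the 4 libraries of a comparison, and each library left out in turn. A weight per group, 1 transcript per symbol and the genotype effect averaged over both regions were added after the data were seen. The table was read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.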

Results

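Polyadenylated RNA was sequenced from trunk pieces of zebrafish embryos aged 38 to 40 hours after fertilisation, in 8 libraries. The embryos were homozygous for the p162 allele of foxc1a, a forkhead transcription factor gene, or were their siblings. Anterior pieces (AS) held somitic segments 1 to 6, the territory that the motor nerves of the pectoral fin cross. Posterior pieces (PS) held segments 7 to about 12, which these nerves do not enter. The 4 groups, MUT_AS, MUT_PS, SIB_AS and SIB_PS, held 2 libraries each, called replicates 1 and 3 after their titles. The deposited table held no counts, so read numbers were inferred from the smallest steps of the values and are known only up to a factor of 2. Relative to the deepest library, SIB_PS replicate 3, MUT_AS replicate 3 held 2.1% of the reads and MUT_AS replicate 1 held 88.9%, while the other 5 libraries held between 9.9% and 32.8%. MUT_AS replicate 3 had 17.5% of transcripts listed at 0, against 4.6% to 8.0% in the other 7 libraries. The standard deviation between replicates, on the log2 scale, was 0.356 in MUT_AS, 0.194 in MUT_PS, 0.181 in SIB_AS and 0.173 in SIB_PS. In a principal component analysis the first component held 77.4% of the variance and separated AS from PS. The second held 9.0% and set MUT_AS replicate 3 (-33.7) apart from the other 7 libraries (-5.1 to 14.8). The labels do not state that the replicates came from separate clutches, so every p below measures only the spread between these libraries.

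The foxc1a transcript was present at like levels in both genotypes. It stood at 17.8 ± 2.1 RPKM (mean and SD, n = 2 in every group) in MUT_AS and 17.2 ± 1.2 in SIB_AS, and at 8.39 ± 0.91 in MUT_PS and 7.53 ± 0.30 in SIB_PS. The log2 difference between mutants and siblings was 0.05 in AS (limma adjusted p = 0.934) and 0.13 in PS (adjusted p = 1). The level of foxc1a therefore does not check the genotype labels. Its paralog foxc1b stood at 15.5 ± 0.96 RPKM in MUT_AS and 12.2 ± 1.2 in SIB_AS, and at 5.48 ± 0.07 in MUT_PS and 4.17 ± 0.058 in SIB_PS. Its log2 differences between mutants and siblings were 0.32 (limma adjusted p = 0.454) and 0.33 (adjusted p = 1). Both genes were higher in AS than in PS of siblings, foxc1a by 1.09 (SE 0.16) and foxc1b by 1.35 (SE 0.15) on the log2 scale. Their adjusted p values in limma were 0.000725 and 0.000268.

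**Figure D1:**
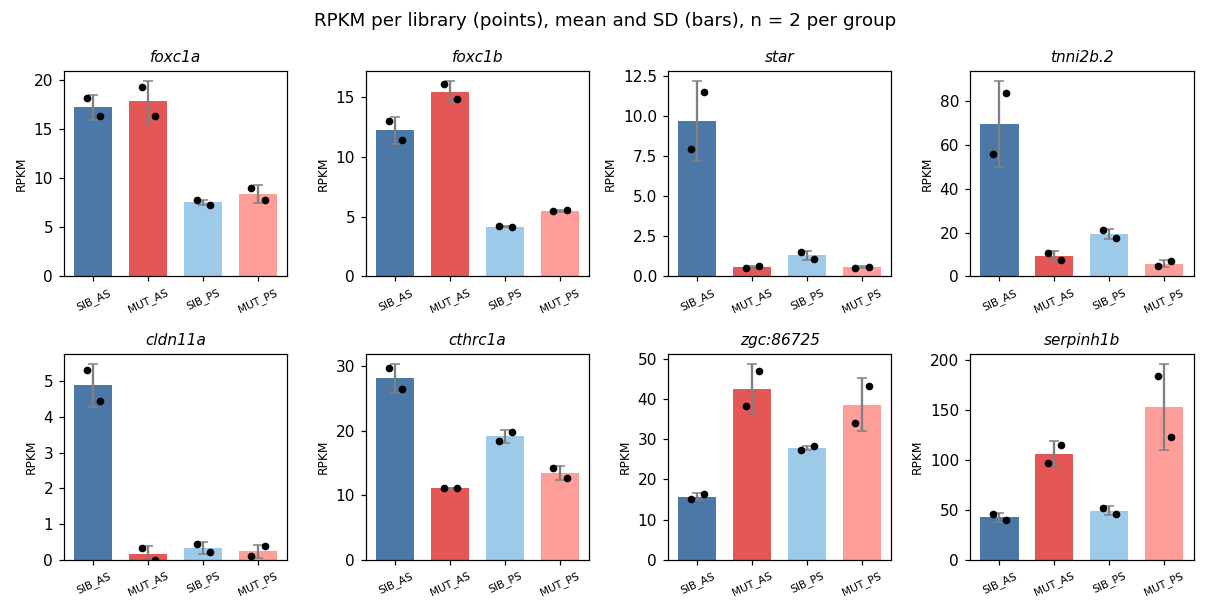
RPKM of 8 genes (y axes, each with its own scale) in the 4 groups (x axes); bars are means, error bars SD and points the 2 libraries of each group. star and cldn11a are near 0 in MUT_AS (mean 0.604 RPKM for star, with 9.72 in SIB_AS), while foxc1a is at 17.8 in MUT_AS and 17.2 in SIB_AS; cldn11a is listed at 0 in MUT_AS replicate 3.

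The first comparison asked which transcripts depend on foxc1a in the segments that the fin nerves cross, MUT_AS against SIB_AS. In MUT_AS 4 genes fell and 1 rose. star, which carries cholesterol into mitochondria for steroid synthesis, fell by 2.72 on the log2(RPKM + 1) scale (SE 0.21, adjusted p = 0.00141 in limma), from 9.72 ± 2.5 RPKM in SIB_AS to 0.604 ± 0.065 in MUT_AS (SD, n = 2). tnni2b.2, a troponin I of fast muscle, fell by 2.78 (SE 0.25, adjusted p = 0.00325), from 69.5 ± 20 to 9.24 ± 2.4 RPKM. cldn11a, a claudin of tight junctions, fell by 2.35 (SE 0.22, adjusted p = 0.00371), from 5.31 and 4.46 RPKM in the SIB_AS libraries to 0.33 in MUT_AS replicate 1 and a listed 0 in replicate 3. cthrc1a, which encodes a secreted protein with a collagen-like repeat, fell by 1.27 (SE 0.15, adjusted p = 0.0213). zgc:86725 rose by 1.38 (SE 0.18, adjusted p = 0.0296), from 15.6 ± 0.92 to 42.6 ± 6.2 RPKM. star, cldn11a and zgc:86725 lie outside the rule for named genes and were chosen after their values were seen. In each of the 5 genes both MUT_AS libraries lay on the same side of both SIB_AS libraries.

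Of 10889 transcripts tested in limma, 1270 had an unadjusted p under 0.05 in AS, and the median over all transcripts was 0.08. Among transcripts with a mean of at least 5 RPKM, groups that do not overlap and a symbol that is not a clone name, those nearest to a call without reaching it were higher for serpinh1b, the collagen chaperone Hsp47 (log2 difference 1.29, adjusted p = 0.108), arrdc3b (0.83), pvalb8 (0.91), hoxb9a (0.79) and dap1b (1.31). They were lower for the fast myosin heavy chain myhz1.2 (-1.30, adjusted p = 0.0946), clic5a (-1.13), the fast myosin light chain mylpfb (-0.83), sprb (-0.97) and apobec2a (-0.90). Leaving out a library gave 1105 calls without MUT_AS replicate 1, 78 without MUT_AS replicate 3, and 2 or 3 without any of the other 6. In these fits star and tnni2b.2 were always called and cldn11a in all but that without SIB_AS replicate 1 (adjusted p = 0.0773), while cthrc1a and zgc:86725 were called only without a MUT_AS library. Each fit with a library left out leaves 1 library in a group, and without a MUT_AS library the wide spread of MUT_AS leaves the fit. These counts and calls therefore cannot decide how firm the 5 genes are. zgc:86725 was also not called with median scaling (adjusted p = 0.113), without a filter (0.151) or with a weight per group (0.0768). cthrc1a was not called without a filter (0.0654) or with a weight per group (0.0768), and cldn11a not with a pseudocount of 0.1 (0.117). With the 4 AS libraries alone, at the same log2 differences, the count was 0 in limma (687 at an unadjusted p under 0.05; the smallest adjusted p was 0.0551). On simulated data with 200 changed genes per set, 16.0% of the calls of this comparison were false, above the nominal 5%, because the MUT_AS libraries spread more than the others.

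Genes of the fast muscle list were lower in MUT_AS. Of its 33 measured members 30 had a lower mean in MUT_AS, 1 (tnni2b.2) fell over all genes and 32 did not pass. Counted as adjusted over the list alone 1 rose and 20 fell. The median log2 difference was -0.57 (-0.78 without SIB_AS replicate 1 and -0.37 without SIB_AS replicate 3), with myhz1.1 at -0.88 beside myhz1.2 and mylpfb. tnni2b.1, the paralog of tnni2b.2, stood at 217 ± 14 RPKM in MUT_AS and 367 ± 50 in SIB_AS (SD, n = 2) and did not pass. Camera gave an adjusted p of 2.53e-19 with the preset correlation and an adjusted p of 0.586 with an estimated correlation. Fry gave an unadjusted p of 0.0149 here, of 0.196 for the same list in PS and of 0.162 in the interaction. For the other lists that camera called in AS, the unadjusted p of fry ran from 0.084 (eye and brain) to 0.547 (pan-neuronal). Among lists that camera called in PS it was at least 0.103 (pigment cell), and in the interaction at least 0.0718 (endothelium). The fast muscle genes held 5.03% and 6.41% of all RPKM in the 2 MUT_AS libraries and 8.24% and 10.5% in the 2 SIB_AS libraries. The slow muscle list, 13 members, had 11 higher in MUT_AS and a median of 0.24 (camera adjusted p = 0.203), with tnnc1b at 0.49 and myoz1b at -0.69. Over all genes and adjusted over the list alone 0 of its members passed in limma. The myogenic regulators (17 members, median -0.01, adjusted p = 0.451) also had 0 members past either threshold.

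Both the anterior and the posterior hox genes had higher values in MUT_AS. In hox paralog groups 1 to 5, 15 of 18 members were higher, with hoxc5a at 0.68, hoxb4a at 0.65 and hoxa3a at 0.64, and the median was 0.33 (camera adjusted p = 0.00623). In hox paralog groups 9 to 13, 10 of 13 were higher, with hoxd10a at 0.67 and hoxa9b at 0.64 beside hoxb9a, and the median was 0.45 (camera adjusted p = 0.00553). Over all genes 0 members of either list passed in limma; adjusted over the list alone 3 and 4 rose. With an estimated correlation the adjusted p was 0.586 for both lists. The call on groups 1 to 5 was lost without MUT_AS replicate 1 (median 0.16, adjusted p = 0.198; without SIB_AS replicate 3 the median was 0.14) and that on groups 9 to 13 without MUT_AS replicate 3 (median 0.28, adjusted p = 0.671). The 8 members of hox paralog groups 6 to 8 had a median of 0.15 (adjusted p = 0.312).

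Camera with the preset correlation called 7 lists of other cell types in AS, none of them with an estimated correlation. The erythroid list had 15 of 15 members higher (median 1.02, camera adjusted p = 0.00111), among them hbbe2 (1.18) and the carbonic anhydrase cahz (1.02). It held 1.01% and 0.36% of RPKM in MUT_AS replicates 1 and 3 against 0.41% and 0.15% in those of SIB_AS, and its median ran from 0.43 without MUT_AS replicate 1 to 1.65 without MUT_AS replicate 3. Its mean log2 value was higher in replicate 1 than in replicate 3 in MUT_AS (5.49 and 4.25) and in SIB_AS (4.37 and 3.47). Leaving out 1 of these libraries therefore unbalances the title endings, which moves the median. The eye and brain list had 10 of 12 members lower (median -0.51, adjusted p = 0.000826), with otx1a at -1.08 and otx2 at -0.70. The periderm and epidermis list was higher (median 0.36, adjusted p = 0.00121; epcam 0.58). The pan-neuronal (median -0.17, adjusted p = 0.00622; stmn2b -0.39), liver gut and pancreas (median -0.14, adjusted p = 0.012; apoa4 -1.30), pigment cell (median -0.05, adjusted p = 0.0242) and spinal progenitor and glia (median -0.05, adjusted p = 0.0474) lists were lower. Over all genes 0 members of these 7 lists passed in limma; adjusted over the list alone 1 member of the eye and brain list and 1 of the liver gut and pancreas list fell. With an estimated correlation the adjusted p was 0.586 for each of these 7 lists. Calls were lost without MUT_AS replicate 1 for erythroid (adjusted p = 0.367), liver gut and pancreas (0.139), pigment cell (0.461) and spinal progenitor and glia (0.382). Without MUT_AS replicate 3 they were lost for pan-neuronal (0.536), liver gut and pancreas (0.0677), spinal progenitor and glia (0.0551) and periderm and epidermis (0.953, where camera pointed lower relative to other genes and the median was 0.16). Without SIB_AS replicate 1 they were lost for eye and brain (0.071), pan-neuronal (0.104), spinal progenitor and glia (0.309), liver gut and pancreas (0.0601) and periderm and epidermis (0.0846), and without SIB_AS replicate 3 for erythroid (0.11) and pigment cell (0.303). With an AS library left out the medians ran from -0.55 to -0.27 for eye and brain, 0.16 to 0.58 for periderm and epidermis, -0.35 to 0.04 for pan-neuronal, -0.33 to 0.01 for liver gut and pancreas, -0.15 to -0.01 for pigment cell and -0.13 to -0.04 for spinal progenitor and glia.

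Axon guidance genes were not called as a group between MUT_AS and SIB_AS. Of 79 measured members of the list fixed in advance, 0 passed over all genes and 0 adjusted over the list alone in limma. The median log2 difference was 0.07 (camera adjusted p = 0.958), near the 0.08 of all transcripts, and 0.00 after median scaling. The median of the list was -0.01 without MUT_AS replicate 1 and 0.21 without MUT_AS replicate 3, where that of all transcripts was 0.02 and 0.15. The members with the smallest p were boc, a receptor partner of hedgehog signalling (0.50), sema4ba (0.51), and the ephrins efnb1 (0.51) and efna2 (-0.63). Of 97 measured genes that the authors' table marks with the axon guidance term, 0 passed in limma, and the median was 0.03 where camera pointed lower (unadjusted p = 0.685). The motor neuron list (14 members, median -0.05, adjusted p = 0.211) had 0 members past the threshold over all genes and 1 lower adjusted over the list alone. Its smallest p was that of olig2 (-0.56), which marks motor neuron and oligodendrocyte progenitors. The somite segmentation and Foxc list (12 members, median -0.02, adjusted p = 0.122) had 1 lower member adjusted over the list alone, with ripply1 at -0.80. Its camera call was made only without SIB_AS replicate 3 (adjusted p = 0.0398). The other lists passed in neither direction, with a camera adjusted p of 0.112 or more. Medians were 0.20 for pectoral fin bud (tbx5a 0.51), 0.23 for pronephros, 0.24 for notochord, 0.22 for immediate early and heat shock (dnajb1b 0.92), 0.13 for the retinoic acid pathway (cyp26a1 0.78) and 0.12 for myeloid (mpx -1.04). With an AS library left out they ran from 0.05 to 0.37 for notochord and 0.10 to 0.24 for immediate early and heat shock. The range was 0.01 to 0.19 for the retinoic acid pathway and -0.01 to 0.23 for myeloid. Medians were -0.11 for endothelium, -0.05 for dermomyotome and sclerotome, -0.03 for the p53 pathway and cell death, -0.02 for connective tissue matrix and 0.08 for cell cycle. Without MUT_AS replicate 1 the median was -0.17 for cell cycle and 0.09 for connective tissue matrix. Without MUT_AS replicate 3 these were 0.29 and -0.19. A call was made for pectoral fin bud without SIB_AS replicate 1 (adjusted p = 0.015), notochord without SIB_AS replicate 3 (0.0398) and connective tissue matrix, as lower, without MUT_AS replicate 3 (0.00824). The heart list had a median of 0.30 while camera pointed lower (adjusted p = 0.776). The median of the heart list turned with single libraries, to -0.88 without MUT_AS replicate 1 and -0.47 without SIB_AS replicate 3, and was 1.62 without MUT_AS replicate 3 and 1.32 without SIB_AS replicate 1. These turns follow the title ending in both genotypes. The mean log2 value of the list was 3.05 in MUT_AS and 2.6 in SIB_AS in replicate 1, and 1 and 1.07 in replicate 3. Leaving out 1 AS library therefore unbalances the title endings between the genotypes. In AS the p53 list had a mean of 0.07 where its median and camera pointed lower (adjusted p = 0.646).

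**Figure D2:**
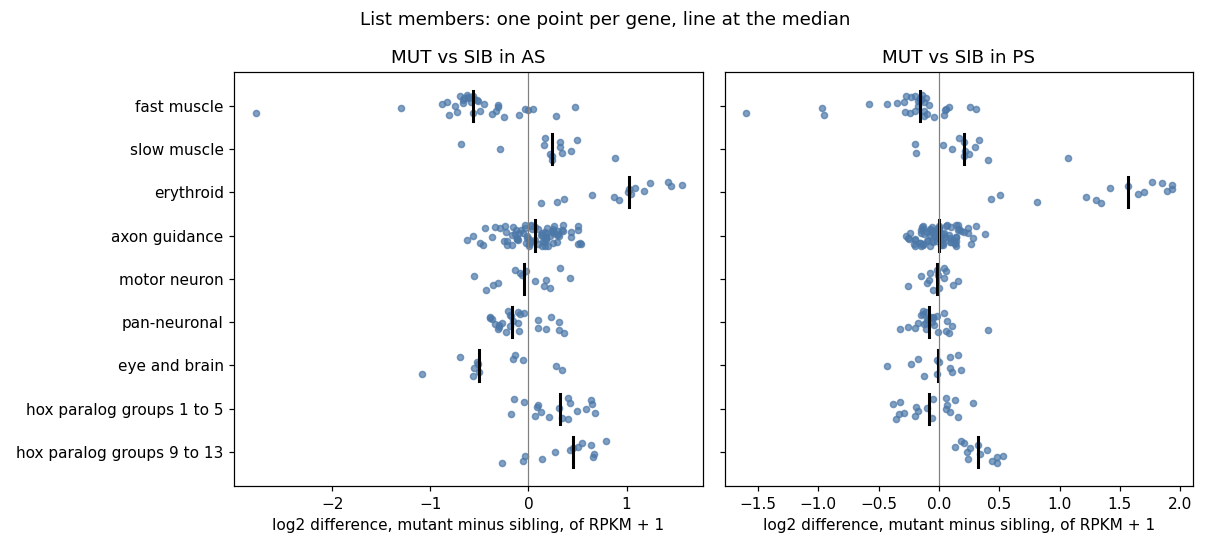
Log2 difference between mutants and siblings (x axes, log2(RPKM + 1) units) of each measured member of 9 gene lists (y axes), in AS on the left and PS on the right, each panel with its own x scale; points are genes and lines medians. The fast muscle list has a median of -0.57 in AS and -0.16 in PS, the erythroid list 1.02 and 1.57, and the axon guidance list 0.07 and 0.00.

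The same question was asked in PS, next to the fin nerve territory, by comparing MUT_PS with SIB_PS. No single gene was called in PS: the count was 0 in limma, with 291 transcripts at an unadjusted p under 0.05. By the same conditions as in AS, the transcripts nearest to a call were higher for serpinh1b (log2 difference 1.60, SE 0.21, adjusted p = 0.0937), the water channel aqp1a.1 (0.83), vsg1 (0.85), tspo (0.70) and the heat shock gene dnajb1b (0.77). They were lower for lyz, the lysozyme of neutrophils and macrophages (-1.36, SE 0.18, adjusted p = 0.0937), for the neutrophil metalloprotease genes npsnl (-1.03) and npsn (-1.02), for tnni2b.2 (-1.60) and for s100t (-1.17). The adjusted p was 0.150 for npsnl, npsn and tnni2b.2 and 0.404 for s100t. npsnl and npsn kept nearly the same ratio in every library (4.92 ± 0.33 and 4.32 ± 0.29 RPKM in MUT_PS, 11.1 ± 0.81 and 9.76 ± 0.7 in SIB_PS), so they are not independent. The myeloid list as a whole had 11 of 17 members higher in MUT_PS and a median of 0.10, and 0 passed over all genes in limma, while 2 fell adjusted over the list alone. For the myeloid list camera pointed lower (adjusted p = 0.0648; 0.0257 without MUT_PS replicate 3 and 0.0452 without SIB_PS replicate 3). lyz stood at 20.1 ± 0.73 RPKM in MUT_PS and 53.4 ± 5.5 in SIB_PS (SD, n = 2), and serpinh1b at 154 ± 43 and 49.1 ± 4.5. The main fit shares 1 spread over all libraries, and the SD between replicates was 0.356 in MUT_AS, 0.194 in MUT_PS and 0.173 in SIB_PS. On simulated data it recovered 74.6% of genes in PS at a log2 change of 1, against 97.6% with a weight per group. With that weight 3 genes were called in AS. The 0 calls in PS beside 5 in AS therefore do not show a smaller genotype effect in PS. The count rose to 15 without MUT_AS replicate 1, 12 without MUT_AS replicate 3, 99 with the 4 PS libraries alone and 17 with a weight per group, and it was 2 with a mean of at least 5 RPKM.

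Camera with the preset correlation called 8 lists between MUT_PS and SIB_PS, none of them with an estimated correlation. The erythroid list had 15 of 15 members higher in MUT_PS (median 1.57, camera adjusted p = 6.28e-17), with cahz at 1.93 and hbbe2 at 1.89. It held 1.59% and 0.52% of RPKM in MUT_PS replicates 1 and 3 against 0.31% and 0.24% in those of SIB_PS. Without MUT_PS replicate 1 the median of the erythroid list was 0.87 and the list stayed called (adjusted p = 4.72e-05); without MUT_PS replicate 3 the median was 2.26. The mean log2 values were 6.16 and 4.79 in MUT_PS and 4.18 and 3.92 in SIB_PS. The heart list, with means of 2.22 and 0.65 in MUT_PS and 0.77 and 0.80 in SIB_PS, had a median of 0.76 (-0.06 without MUT_PS replicate 1 and 1.57 without MUT_PS replicate 3) and was not called (camera adjusted p = 0.578; 0.017 without MUT_PS replicate 3). The fast muscle list had 27 of 33 members lower (median -0.16, or -0.27 without SIB_PS replicate 1 and -0.06 without SIB_PS replicate 3; adjusted p = 1.41e-10), and 2 fell adjusted over the list alone. Hox paralog groups 9 to 13 had 13 of 13 members higher (median 0.32, adjusted p = 2.66e-05; hoxa11b 0.53, hoxa13b 0.48). Groups 1 to 5 had 11 of 18 lower (median -0.08, adjusted p = 0.00863; hoxb4a -0.38). The pigment cell (17 of 18 higher, median 0.20, adjusted p = 0.00658; pts 0.49, slc24a5 0.40), periderm and epidermis (median 0.22, adjusted p = 0.0179) and notochord (median 0.19, adjusted p = 0.0182; ctgfa 0.76) lists were higher. The pan-neuronal list was lower (median -0.08, adjusted p = 0.00863). Over all genes 0 members of these 8 lists passed in limma, and adjusted over the list alone 1 notochord gene rose. With an estimated correlation the adjusted p was 0.619 for the erythroid, fast muscle, both hox, pigment cell and notochord lists, 0.696 for pan-neuronal and 0.704 for periderm and epidermis. Calls were lost without MUT_PS replicate 1 for both hox lists (adjusted p = 0.266 each). Without MUT_PS replicate 3 they were lost for pigment cell (0.561), pan-neuronal (0.994), notochord (0.994) and periderm and epidermis (0.124, where camera pointed lower and the median was -0.01). Without SIB_PS replicate 1 they were lost for hox paralog groups 1 to 5 (0.739), notochord (0.453) and periderm and epidermis (0.279), and without SIB_PS replicate 3 for pan-neuronal (0.0509). With a PS library left out the medians ran from -0.25 to 0.11 for hox paralog groups 1 to 5, 0.15 to 0.51 for hox paralog groups 9 to 13, 0.12 to 0.30 for pigment cell, -0.01 to 0.43 for periderm and epidermis, 0.00 to 0.35 for notochord and -0.20 to 0.07 for pan-neuronal.

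In PS the axon guidance list had a median of 0.00, with 0 of 79 members past the threshold over all genes and 0 adjusted over the list alone in limma. Camera gave an adjusted p of 0.0711, which passed as lower without MUT_PS replicate 3 (0.00148) and without SIB_PS replicate 1 (0.00501). The 2 genotype comparisons shared 0 called genes, since PS had none. Across transcripts, which are not independent replicates, their log2 differences correlated with r = 0.33 (rho = 0.29), and they have no library in common. However, deviations of AS and PS libraries with the same title ending correlated with 0.22 in mutants and 0.52 in siblings. Such shared deviations can raise r, so r does not by itself show a shared genotype effect.

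The third comparison asked how the fin nerve territory differs from its neighbour in siblings, SIB_AS against SIB_PS. In SIB_AS the hormone genes of the endocrine pancreas, ins (log2 difference 4.01, SE 0.71), gcgb (3.70) and sst2 (3.66), were higher. So were the ear genes stm (3.82), otomp (3.61) and atoh1b (3.30), the anterior hox gene hoxb5b (3.53, SE 0.28), the pharyngeal genes barx1 (3.12) and tbx1 (2.76), and cyp26c1 (3.01), which degrades retinoic acid. The labels state that heads were removed, and whether tissue of the ear or pharynx remained in the AS pieces was not tested. Lower in SIB_AS were the fast myosin heavy chain myhz2 (-5.08, SE 0.20), the actinodin genes of the fin fold and1 (-3.45) and and3 (-3.35), stc1l (-3.47), the renal sodium chloride carrier slc12a3 (-3.31), c1qtnf9 (-3.07), atp1a1a.3 (-2.74), mfsd4b (-2.67) and the posterior hox genes hoxb10a (-2.66) and hoxc9a (-2.47). The adjusted p values of these 20 genes in limma ran from 2.70e-06 for myhz2 to 0.00868 for gcgb.

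Of the 10889 transcripts, 4531 were higher and 1047 lower in SIB_AS, and 1928 of these 5578 had an absolute log2 difference of at least 1. The median over all transcripts was 0.40; with every library scaled to the same median, which removes this shift, 2067 were higher and 2299 lower. The count was 3288 without SIB_AS replicate 1 and 3161 without SIB_PS replicate 3.

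Hox genes followed their paralog groups along the trunk. In groups 1 to 5, 16 of 18 members rose and 0 fell (median 1.73, camera adjusted p = 3.19e-06), with hoxb4a at 2.66, hoxd4a at 2.41 and hoxc5a at 2.23. In groups 6 to 8, 6 rose and 2 fell (median 0.95, adjusted p = 0.294). In groups 9 to 13, 1 rose and 11 of 13 fell (median -1.83, adjusted p = 1.18e-12), with hoxa9b at -2.41 and hoxd9a at -1.96. With an estimated correlation the adjusted p was 0.458 for groups 1 to 5 and 0.264 for groups 9 to 13. Adjusted over the list alone the counts in the 3 lists were the same, and with median scaling 15 members of groups 1 to 5 rose and 11 of groups 9 to 13 fell.

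**Figure D3:**
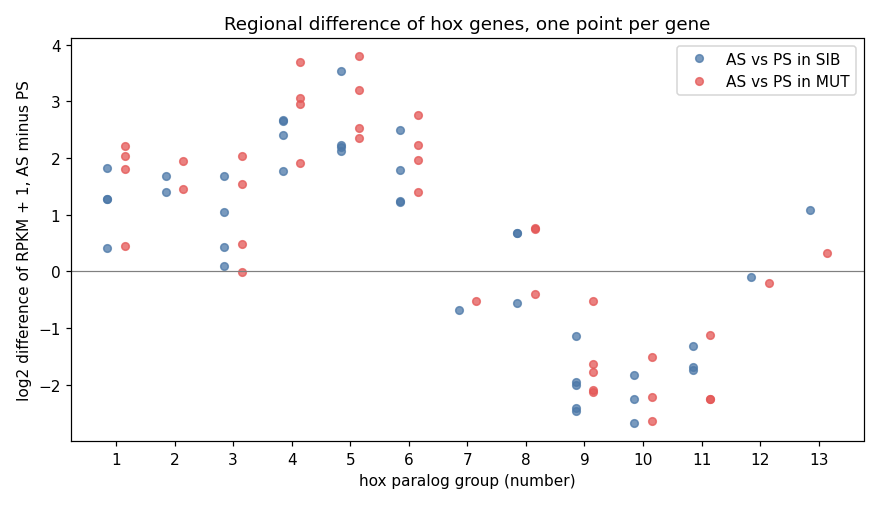
Log2 difference between AS and PS (y axis, log2(RPKM + 1) units) of each measured hox gene by paralog group (x axis), in siblings (blue) and mutants (red). Groups 1 to 5 have a median of 1.73 in siblings and 2.03 in mutants, and groups 9 to 13 of -1.83 and -1.77.

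Neural and proliferation genes were higher in SIB_AS and muscle genes lower. Of the axon guidance list 51 rose and 3 fell among 79 (53 and 4 adjusted over the list alone; 31 and 5 with median scaling), with efna2 at 2.04, dpysl3 at 1.60, dpysl2b at 1.49 and sema3bl at 1.48. For axon guidance camera gave an adjusted p of 0.000575 (adjusted p = 0.463 with an estimated correlation). In the pan-neuronal list 19 of 26 rose and 0 fell (10 and 1 with median scaling; tubb5 2.13, elavl3 1.95; adjusted p = 0.00451, and adjusted p = 0.569 with an estimated correlation). In the cell cycle list 25 of 26 rose and 0 fell (ccna2 1.38, mcm7 1.37; adjusted p = 5.33e-06, and adjusted p = 0.486 with an estimated correlation). Camera also placed higher, relative to other genes, the spinal progenitor and glia list (16 of 20 rose; fabp7a 2.05), the retinoic acid pathway (16 of 21 rose and 1 fell; rarga 2.36, rxrga 2.28, crabp1b 2.07), the eye and brain list (11 of 12 rose; eng2b 2.77, dmbx1a 2.31) and somite segmentation and Foxc (9 of 12 rose and 1 fell; hes6 1.58). The camera adjusted p was at most 0.0486 for these 4 lists, and the adjusted p was 0.458 to 0.569 under an estimated correlation. The motor neuron list had 7 of 14 members higher and 0 lower, with phox2bb at 2.11 and mnx1 at 1.56, but with median scaling 4 were higher and 3 lower, and camera gave an adjusted p of 0.5.

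The fast muscle list had 29 of 33 members lower and 1 higher (median -1.28, camera adjusted p = 2.35e-25), with pvalb3 at -2.17 and acta1b at -1.43. The higher member was tnni2b.2 (1.77), the only member called over all genes between MUT_AS and SIB_AS, so its regional pattern is opposite to that of the list. The slow muscle list had 9 of 13 lower and 1 higher (median -1.31, adjusted p = 2.86e-08; smyhc1 -1.47). Both had an adjusted p of 0.217 under an estimated correlation. Camera placed lower, relative to other genes, the connective tissue matrix (8 fell and 4 rose of 29; 17 and 1 with median scaling), periderm and epidermis (9 fell of 23; 20 with median scaling), liver gut and pancreas (13 fell and 7 rose of 25), notochord (6 fell and 3 rose of 13), pronephros (9 fell and 7 rose of 21), myogenic regulators (5 fell and 1 rose of 17; myf6 -1.55, myod1 -1.43) and erythroid (0 of 15 passed in limma) lists. The camera adjusted p was at most 0.0339 for these 7 lists, and the adjusted p was 0.217 to 0.645 under an estimated correlation. The median of the pronephros list was 0.04 and that of the myogenic regulators 0.06, above 0 where the test and the mean were below, and both turned negative with median scaling. Among the pectoral fin bud genes 15 rose and 6 fell of 27 (10 and 8 with median scaling), with a median of 0.58 where camera, relative to other genes, pointed lower (adjusted p = 0.673). The camera call was lost for somite segmentation and Foxc without either MUT_AS library (adjusted p = 0.0802 and 0.0803), without either MUT_PS library (0.0534 and 0.0532) and without SIB_AS replicate 1 (0.0588). For the erythroid list it was lost without SIB_AS replicate 3 (0.452) and without SIB_PS replicate 1 (0.0585).

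The same regional comparison in mutants gave sst2 (log2 difference 4.97, SE 0.51), hoxb5b (3.80), stm (3.72), hoxb4a (3.69) and ins (3.50) as the named genes higher in MUT_AS than in MUT_PS. Those lower were myhz2 (-5.43, SE 0.20), and3 (-4.10), and1 (-4.06), stc1l (-3.96) and slc12a3 (-3.57). In limma 4796 transcripts were higher and 1189 lower, and 2449 of these 5985 had an absolute log2 difference of at least 1. With median scaling, which removes a shift of 0.41, 2343 were higher and 2455 lower. Hox paralog groups 1 to 5 had 16 of 18 members higher and 0 lower (median 2.03), and groups 9 to 13 had 11 of 13 lower and 0 higher (median -1.77). The fast muscle list had 30 of 33 lower and 0 higher (median -1.63) and the axon guidance list 57 of 79 higher and 2 lower (median 0.84; efnb3b 2.36). Their camera adjusted p values were 1.44e-06, 1.78e-11, 2.81e-27 and 0.00024, and their adjusted p values with an estimated correlation 0.402, 0.305, 0.274 and 0.492. Called genes shared by both genotypes numbered 4025 higher and 833 lower, where 1996 and 114.3 would be shared by chance, and 2 went in opposite directions. With median scaling 1713 higher and 1906 lower were shared, where 444.8 and 518.3 would be by chance. Across transcripts the log2 differences correlated with r = 0.92 between libraries that do not overlap.

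The difference between the genotype effects in AS and in PS was tested as an interaction. The genes closest to a call were lyz (log2 difference of differences 1.80, adjusted p = 0.119), star (-2.17, adjusted p = 0.119) and cldn11a (-2.24, adjusted p = 0.119), none of which passed. The log2 difference of lyz was -1.36 in PS and 0.44 in AS, that of star -0.55 and -2.72, and that of cldn11a -0.10 and -2.35. The next genes that met the conditions for naming were npsnl (1.06), npsn (1.05), cyp26a1 (1.04) and s100t (1.37), and, with the opposite sign, the apolipoproteins apoa4 (-1.85) and apoea (-1.48), clic5a (-1.07), ypel3 (-1.14) and rilpl1 (-0.92). The count was 0 in limma (298 at an unadjusted p under 0.05), so star and cldn11a, called in AS, are not shown to differ between the regions. In SIB_PS star stood at 1.32 ± 0.29 RPKM and cldn11a at 0.33 ± 0.16. On the log2(RPKM + 1) scale neither could fall in PS by as much as in AS, so the interaction cannot compare their genotype effects. Without MUT_AS replicate 1 the count was 199 and without MUT_AS replicate 3 it was 11.

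Among the lists, fast muscle genes were lower in mutants by more in AS than in PS (interaction median -0.34, camera adjusted p = 9.19e-08), and hox paralog groups 1 to 5 were higher in AS relative to PS (0.31, adjusted p = 6.03e-06; hoxb4a 1.03, hoxc5a 0.97). With an estimated correlation the adjusted p was 0.587 for both, and in limma 0 members of either passed over all genes, with 2 of the hox genes higher adjusted over the list alone. These 2 calls held without each library in turn. The axon guidance list had an interaction median of 0.06 (adjusted p = 0.284), which passed without MUT_PS replicate 3 (0.0419).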

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

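All tests of explanations in this part were chosen only after the results were seen; the test of the spread and that of pieces taken further back were redefined after their outcomes were known, and the interaction tests of the lists were planned. In 8 lists the genotype effect differed between AS and PS by the interaction test of camera with the preset correlation, and in none with an estimated correlation.

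The 4 genes that fell in MUT_AS were weighed first. If the shallow depth of MUT_AS replicate 3 had made the 4 falls, they would shrink without that library. The log2 differences were then -2.76 for star, -2.53 for tnni2b.2, -2.14 for cldn11a and -1.27 for cthrc1a. With both libraries they were -2.72, -2.78, -2.35 and -1.27, so the falls do not rest on that library alone. Their calls cannot decide this, since MUT_AS then holds 1 library and its wide spread leaves the fit. Posterior tissue in the MUT_AS pieces would need a share of 94.6% to 115.9% to account for the 4 falls, while 13 genes outside the hox clusters that are at least 4-fold higher in PS gave a median implied share of 0% (quartiles -1.21% to 3.63%), which argues against it. In siblings all 4 were higher in AS than in PS (log2 difference 2.19 for star, 2.15 for cldn11a, 1.77 for tnni2b.2 and 0.53 for cthrc1a). Whether the MUT_AS pieces lacked anterior tissue that holds these transcripts was not tested. A larger spread between the MUT_AS libraries than the fit assumes stays open, since with a weight per group, at the same log2 differences, 3 of the 4 falls were called (SE of star 0.21 before and 0.28 after; cthrc1a 0.15 and 0.21, adjusted p = 0.0768), and with the 4 AS libraries alone, which leave fewer residual degrees of freedom, none were (adjusted p = 0.0551 for star and tnni2b.2, 0.116 for cldn11a and 0.268 for cthrc1a). An effect of the genotype also stays open, as untested beyond these libraries.

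Fast muscle genes were lower in mutants by more in AS than in PS, with medians of -0.57 (-0.78 to -0.37 with an AS library left out) and -0.16 (-0.27 to -0.06 with a PS library left out), an interaction median of -0.34 and a camera adjusted p of 9.19e-08 (adjusted p = 0.587 with an estimated correlation). Less muscle of every kind in the MUT_AS pieces would lower slow muscle genes too, but their median was 0.24 (quartiles 0.17 to 0.34). The shallow depth of MUT_AS replicate 3 would end the difference without that library, but the median was then -0.59 (quartiles -0.75 to -0.41). A loss of fast fibres alone, less of these transcripts per fibre, a difference in stage and the genotype stay open as untested explanations.

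Hox paralog groups 1 to 5 had an interaction median of 0.31, from 0.33 in AS and -0.08 in PS (camera adjusted p = 6.03e-06; adjusted p = 0.587 with an estimated correlation), and groups 9 to 13 were also higher in MUT_AS. MUT_AS pieces taken further back along the trunk would lower groups 1 to 5, and their median was 0.33 (quartiles 0.09 to 0.47) and stayed above 0 with each AS library left out (0.14 to 0.45), but this stays open, since without MUT_AS replicate 1 the lower quartile was -0.07. The eye and brain list, with 11 of 12 members higher in AS than in PS of siblings, had 10 of 12 lower in MUT_AS (median -0.51). That is the direction such pieces would give. Posterior tissue with the make-up of the whole PS pieces would raise all genes of PS alike. But 11 members of groups 9 to 13 gave a median implied share of 9.8% (quartiles 5.2% to 15.5%), against 0% (upper quartile 3.63%) for the 13 other genes. In MUT_AS replicate 3 alone these shares were 12.8% (lower quartile 7.45%) and -0.08% (upper quartile 4.16%). This cannot decide on tissue from only the front of PS, which need not have that make-up. The 13 genes also include the fast muscle genes myhz2 (-0.1%) and pvalb3 (0%), of a list lower in MUT_AS. Whether groups 9 to 13 rest on MUT_AS replicate 3 cannot be told apart from a genotype effect, since without it their median was 0.28 with quartiles of -0.06 to 0.46. In PS, which has no library in common with AS, 13 of 13 were higher (median 0.32, or 0.15 without MUT_PS replicate 1). Camera gave an adjusted p of 2.66e-05 there, and of 0.619 with an estimated correlation. AS and PS libraries with the same title ending deviated together, however (correlations of 0.22 in mutants and 0.52 in siblings). Groups 1 to 5 had 11 of 18 lower in PS (median -0.08, or -0.25 to 0.11 with a PS library left out). Lower groups 1 to 5 with higher groups 9 to 13 is also the direction that MUT_PS pieces taken further back would give, which was not tested. The PS values therefore cannot decide for a genotype effect.

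The other 6 lists are given as values. The pigment cell list had an interaction median of -0.22, from -0.05 in AS and 0.20 in PS (camera adjusted p = 2.79e-05; adjusted p = 0.587 with an estimated correlation; lost without MUT_AS replicate 1, 0.0582). The endothelium list had -0.30, from -0.11 and 0.12 (0.00661; 0.587; lost without MUT_AS replicate 1, 0.0582, MUT_AS replicate 3, 0.063, or SIB_AS replicate 1, 0.0892). The erythroid list had -0.37, from 1.02 and 1.57 (0.0302; 0.873; lost without MUT_AS replicate 3, 0.937, SIB_AS replicate 1, 0.831, or SIB_PS replicate 1, 0.0579, and without MUT_PS replicate 1, where camera pointed the other way, 0.429). The liver gut and pancreas list had -0.15, from -0.14 and 0.11 (0.0104; 0.769; lost without MUT_AS replicate 1, 0.0582, MUT_AS replicate 3, 0.0674, SIB_AS replicate 1, 0.0536, or SIB_PS replicate 3, 0.249). The list of hox paralog groups 6 to 8 had 0.16, from 0.15 and -0.07 (0.0313; 0.769; lost without MUT_AS replicate 1, 0.151, MUT_AS replicate 3, 0.0964, MUT_PS replicate 3, 0.0534, SIB_AS replicate 1, 0.285, or SIB_PS replicate 1, 0.232). The eye and brain list had -0.38, from -0.51 and -0.01 (0.0104; 0.587; lost without MUT_AS replicate 1, 0.0582, or SIB_AS replicate 1, 0.357). In each case the values in parentheses are the camera adjusted p, the adjusted p with an estimated correlation and the adjusted p without the library named.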

How the results depend on the processing

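A weight per group and 1 transcript per symbol were chosen after the data were seen, and all other alternatives were planned; count-based alternatives were not run, since the table holds no counts. Calls of MUT against SIB in AS (5) were 3 without a filter, 3 with a mean of at least 5 RPKM, 3 with a weight per group, 0 with only the 4 libraries of the comparison (limma; 687 at an unadjusted p under 0.05), and 2 to 1105 with a library left out. Calls in PS (0 in limma, 291 at an unadjusted p under 0.05) were 2 with a mean of at least 5 RPKM, 17 with a weight per group, 99 with only its 4 libraries, and 0 to 15 with a library left out; the interaction (0, and 298) gave 0 to 199. AS against PS gave 5578 in SIB (3161 to 6967 with a library left out, 1928 at an absolute log2 difference of at least 1) and 5985 in MUT (4156 to 6831, and 2449). A group left with 1 library was assumed to vary like the others. Lists past the threshold numbered 10, 8, 18, 17 and 8 in AS, PS, SIB, MUT and the interaction, and 0 in each with an estimated correlation; leaving a library out gave 5 to 10, 6 to 14, 17 to 18, 14 to 17 and 4 to 13. Median scaling, both pseudocounts and 1 transcript per symbol kept the total of calls of each of these 5 comparisons within 1.5 times, as did the replicate block (7, 0, 5976, 6330 and 0 calls; 9, 10, 17, 17 and 9 lists). Median scaling changed the split by direction of AS against PS, from 4531 higher and 1047 lower to 2067 and 2299 in SIB and from 4796 and 1189 to 2343 and 2455 in MUT. Adjusted p values in AS over the alternatives ran from 7.47e-05 to 0.117 for cldn11a, 0.00163 to 0.315 for cthrc1a and 0.000772 to 0.318 for zgc:86725. Libraries with the same title ending deviated from their group means with correlations of -0.09 to 0.52. The direction of camera, relative to other genes, turned for periderm and epidermis in AS without MUT_AS replicate 3 (adjusted p = 0.953; 1.96e-06 to 0.953 with a library left out), where the median stayed above 0 (0.16), for the same list in PS without MUT_PS replicate 3 (0.124; 4.17e-08 to 0.279; median -0.01), and for erythroid in the interaction without MUT_PS replicate 1 (0.429; 5.05e-10 to 0.937). The log2 difference turned for dct, AS against PS in SIB, from 0.45 to -0.02 with median scaling, which removes the shift of 0.40. For the other changes the cause was not tested. The depth of MUT_AS replicate 3 limits its low values, with 2555 transcripts at 0.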

Other observations

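The averaged genotype effect, the heme synthesis list and the weight per group in this part were chosen only after the results were seen. Averaged over AS and PS, the genotype effect was called in limma for 9 genes, of which 4 were higher and 5 lower in mutants. This fit takes the AS and PS libraries as independent. Deviations of AS and PS libraries with the same title ending correlated with 0.22 in mutants and 0.52 in siblings, so the SE may be too small. serpinh1b, the collagen chaperone Hsp47, was higher by 1.44 on the log2 scale (SE 0.15, adjusted p = 0.00673), at 106 ± 13 RPKM in MUT_AS and 42.7 ± 4.6 in SIB_AS, and at 154 ± 43 in MUT_PS and 49.1 ± 4.5 in SIB_PS (SD, n = 2). The parathyroid hormone gene pth1b was higher by 1.26 (SE 0.15, adjusted p = 0.0216), at 5.40 ± 2.0 RPKM in MUT_AS and 1.34 ± 0.17 in SIB_AS. The water channel aqp1a.1, found in endothelium and red cells, was higher by 0.79 (SE 0.11, adjusted p = 0.0289), at 40.7 ± 0.52 RPKM in MUT_PS and 22.5 ± 0.65 in SIB_PS, and zgc:86725 by 0.92. tnni2b.2 (-2.19), star (-1.63), cldn11a (-1.23), myhz1.2 (-1.14) and cthrc1a (-0.88) were lower. The count was 19 with the replicate block, 720 without MUT_AS replicate 1 and 69 without MUT_AS replicate 3. It was 0 without SIB_PS replicate 1 in limma (850 transcripts at an unadjusted p under 0.05) and 2 to 4 without any of the other 5.

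The 12 measured genes of heme synthesis, which red cells need for haemoglobin, had a median log2 difference of 0.80 between mutants and siblings in PS and 0.58 in AS (0.18 without MUT_AS replicate 1). Adjusted over the list alone 6 rose in PS and 0 in AS in limma. In PS camera gave an unadjusted p of 6.18e-09 with the preset correlation and an unadjusted p of 0.0983 with an estimated correlation. Without MUT_PS replicate 1 the median of heme synthesis in PS was 0.38 (unadjusted p = 0.00774), and its mean log2 value in MUT_PS replicate 3 was 3.26, beside 3.04 and 2.95 in SIB_PS. alas2, the first enzyme of the pathway in red cells, stood at 30.5 ± 24 RPKM in MUT_PS and 7.58 ± 1.7 in SIB_PS (SD, n = 2), and ppox at 4.73 ± 2.5 and 1.62 ± 0.22; neither passed over all genes. With a weight per group, 17 transcripts were called in PS. Among the 12 lower were lyz (-1.36, adjusted p = 0.00134), npsnl (-1.03, adjusted p = 0.0145), npsn (-1.02, adjusted p = 0.0145) and the clock gene per1b (-1.22, adjusted p = 0.0235) in limma. mpx of the myeloid list (-0.81, adjusted p = 0.0439 in limma) and another transcript of npsn (-0.92, adjusted p = 0.0439) were also among the 12. npsnl and npsn kept nearly the same ratio in every library. The myeloid list as a whole had 11 of 17 members higher in PS and a median of 0.10.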
